A study of Homo sapiens with 12 samples.

How the data were processed

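Transcripts were measured in 6 cultures of human blood monocytes, 3 with SLE serum and 3 with autologous serum, each at 20% for 6 hours and each hybridized to 2 types of Affymetrix array, the A and B arrays of the HG-U133 set (array A and array B). Per the labels' protocols, cells stood in multi-well plates in medium with glutamine and antibiotics, RNA was isolated with a column kit or a kit for small samples depending on cell number, and the label was made by amplification over 2 cycles. The protocols name a pair of plate formats, and which culture used which is not given in the sources used here. The deposited values are intensities, 1 positive linear signal per probe set, and the authors had scaled each array, as the deposited values show, to a mean signal of 500.2 or 500.3 after trimming 2% at each end. The software, its version and the background correction are not given in the sources used here. Arrays A and B were scaled apart, so signals were not compared between them, and no detection calls were used here.

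Groups came from the sample labels, and the code in the sample titles paired each SLE serum culture with 1 autologous culture. That a pair shares its monocyte donor follows from the word autologous and the shared code, as the labels do not state it outright. The series design text sets SLE serum against autologous serum, so the pair was a block in the fit. In a check of the pairing, the correlations of same-numbered samples' deviations from their group means were -0.10, 0.02 and -0.04 on array A and -0.05, 0.03 and -0.03 on array B, so the pairing could not be seen in the values. In the fit with pairs as a block, 0 probe sets had a pair effect on either array (limma with Benjamini-Hochberg adjustment; 3.46% and 3.71% at an unadjusted p under 0.05). Of the 6 ways to pair the cultures, some had a lower median residual variance than the labelled one. The lowest was 0.0732 against 0.0856 on array A, and 0.116 against 0.137 on array B. The block thus rests on the titles and not on the values. The fit with no replicate block gave 3847 changed probe sets on array A and 2041 on array B.

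Probe sets were named through the platform annotation, which gave 1 symbol to 19071 probe sets of array A and 15432 of array B, several symbols to 1043 and 554, and none to 2169 and 6659. Of the named ones, 19059 and 15407 matched a gene of the RefSeq table by gene number, and 0 symbols changed. No gene was named from a probe set with several symbols. The 68 control probe sets of each array and the probe sets of sex-linked genes (52 on array A and 32 on array B) were left out of the tests, and 1 set of control probe sets is not reported here. The 100 other probe sets present on both types gave log2 changes that correlated across probe sets with r = 0.955 between arrays A and B. That both arrays of a culture hold the same RNA is per the labels; by deviations from the group means over these probe sets, 5 of 6 array B samples correlated best with the array A sample of the same culture, with a lowest correlation of -0.06 with the own sample and a highest of 0.46 with another.

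The test was limma (version 3.58.1, in R 4.3.3), with lmFit and eBayes with an intensity trend, on log2(signal + pseudocount), two-sided, with Benjamini-Hochberg adjustment within an array type and a threshold of 0.05. The pseudocount was the median over the 6 arrays of the 25th percentile, 32.1 on array A and 63.2 on array B. Fold changes are on this log2(signal + pseudocount) scale, which understates the change of low genes. A probe set was kept if its signal exceeded the pooled median, 113 on array A and 197.4 on array B, in at least 3 of the 6 arrays, which kept 51.8% and 52.4%. No further normalization was applied. Residual and prior degrees of freedom came together to 10.1 on array A and 11.1 on array B; with pairs 1, 2 and 3 left out in turn they were 11487, 74.4 and 9.59 on array A and 14.4, 10.8 and 34.4 on array B, so that without pair 1 the variance on array A was nearly all pooled. Every adjusted p of a gene given with the results is limma's, and every adjusted p of a list is that of limma's camera unless another test is named.

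Where several kept probe sets had the same single symbol, the one with the highest mean stood for the gene. Of 518 genes of array A with at least 2 changed probe sets, 13 (2.51%) had probe sets that moved in opposite directions, and on array B 1 of 198 did. The 27 gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists with 5 or more measured members, 26 on array A and 10 on array B. Each list was also tested with an estimated correlation and with fry. The main p of fry tests whether a list's genes move, on balance, 1 way, and its mixed p whether they change in either direction; neither compares the list with other genes. In addition, 9 lists of markers of other blood cells were read as levels. Genes read by probe sets that near-identical copies share, such as NCF1, FCGR3B and FCGR1BP, are uncertain.

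The groups, the tests, the gene lists, the alternatives and the naming rule were fixed before the data were examined. The rule names the 15 largest rises and 10 largest falls of array A and the 5 and 5 of array B, among genes past the threshold that moved the same way in all 3 pairs, up to 4 members of the smallest p in each list, and a panel of 25 genes whatever their values. Other genes were named after their values were seen, to complete counts of 5 or fewer or as changed markers: IL23A, CCL4, CCL8, MCL1, TLR1, TLR2, TLR4, FCGR1BP, FCGR2A, SERPING1, CX3CR1, FPR1, FCN1, CSF3R, CSF1R, GPNMB, STAB1, F13A1, NFKBIA, THBS1, SGK1, LSS, SREBF1, SLC2A1, PGK1, HK2, TPI1, PKM, SDHC, ASNS, BAG3, HSP90AA1, SLC7A11, IFNGR1, CLEC10A, FCGR3B, GZMB, IL3RA, TCF4, GNG11, and the other markers given with CLEC10A or PPBP. Alternatives were other pseudocounts, filters and scalings, a fit without the trend, a fit with no replicate block, leaving out probe sets with the ending _x_at, the mean of a gene's probe sets, and leaving out each pair; counting genes in place of probe sets was chosen after seeing the data.

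The steps were tested on simulated data, 20 times for each array type, with 100 probe sets changed 4-fold and 100 changed 2-fold. On array A, 82.55% of the 4-fold and 13.05% of the 2-fold changes were recovered, with 5.75 unchanged probe sets among 101.35 called. On array B the shares were 54.8% and 3.85%, with 2.9 among 61.55 called. A shifted list had an unadjusted camera p under 0.05 in 20 of 20 simulations and an unshifted one in 1 of 20. Unlike the list calls in the real data, these were not adjusted over lists and used no intensity trend. Each probe set was drawn independently, whereas real list members can be correlated (estimated at 0.76 for interferon-stimulated genes on array A). The share of false list calls in the real data can therefore be higher. The simulations changed 200 probe sets, far fewer than were called in the real data, so the shares recovered need not carry over. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.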

Results

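The data come from blood monocytes of 3 healthy people that were kept for 6 hours in medium with 20% serum. The serum came either from patients with newly found, untreated systemic lupus erythematosus (SLE), an autoimmune disease marked by antibodies against nuclear material, or from the monocyte donor (autologous serum). The question the design addresses is how SLE serum changes the transcripts of a normal monocyte, with the donor's own serum as the baseline. The 3 cultures with SLE serum and the 3 with autologous serum formed 3 pairs, named pairs 1 to 3 here. RNA of each culture was hybridized to both arrays of the Affymetrix HG-U133 set, called array A and array B, which gave 12 arrays with 22283 probe sets on each array A and 22645 on each array B. Median signals lay between 104.3 and 125.6 on the array A samples with autologous serum and between 109.9 and 115.8 on those with SLE serum. On array B the medians ran from 167.3 to 206.8 with autologous serum and from 196.3 to 215.6 with SLE serum. The number of arrays limits the precision of every value. P-values of genes rest on the spread within these pairs, in large part pooled over probe sets. With 3 pairs they tell little about other patients or donors. No culture with serum of another healthy person was analysed here, so the comparison is between SLE serum and a donor's own serum.

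With SLE serum, monocytes carried more transcript of interferon-stimulated genes, the antiviral program that type I interferon switches on. MX1, a GTPase that blocks viral replication, rose from a signal of 256 ± 35.6 to 20405 ± 8211 (SD, n = 3 cultures each), a 67.8-fold difference (log2 6.08, SE 0.27, limma adjusted p = 1.2e-06). In the other direction, CXCL5, a chemokine that draws neutrophils, fell from 7098 ± 1125 to 31.6 ± 34.5 (SD, n = 3 each; log2 -6.92, SE 0.29, limma adjusted p = 1.2e-06). FABP5, a fatty acid carrier, fell from 16762 to 268.8 (log2 -5.80, SE 0.24, limma adjusted p = 1.2e-06). LPL, the lipase that releases fatty acids from lipoproteins, fell from 10261 to 168.7 (log2 -5.54, SE 0.42, adjusted p = 1.8e-05; log2 -4.89 without pair 1 and -6.26 without pair 3).

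Members of the list of interferon-stimulated genes stood high among the 15 genes with the largest rise on array A. HERC5, which attaches ISG15 to new proteins, rose by 5.94 on the log2 scale (SE 0.36), the antiviral enzyme RSAD2 by 5.88 (SE 0.43), and CXCL10, a chemokine for activated T cells, by 5.80 (SE 0.53). IFI44L rose by 5.80, the RNA-binding protein IFIT1 by 5.26, its relative IFIT2 by 4.90, the ubiquitin-like modifier ISG15 by 5.02, and USP18, which removes ISG15 and dampens the interferon receptor, by 5.00. LY6E, a lipid-anchored surface protein, rose by 4.77, the RNA helicase DHX58 by 4.73, the death ligand TNFSF10 (TRAIL) by 4.68 and the apoptosis regulator XAF1 by 4.51. The rest of the 15 genes were HES1, a repressor downstream of Notch (5.39, SE 0.28), and NCF1, a subunit of the phagocyte oxidase (4.46, SE 0.31). The probe set of NCF1 can also read its near-identical pseudogenes. CXCL10 stands in the list of interferon-gamma-type genes and TNFSF10 in that of TNF family ligands. Next to CXCL5, FABP5 and LPL, the largest falls were those of the secretory granule chaperone SCG5 (-6.26, SE 0.46), the chemokines PPBP (-5.76, SE 0.34) and CXCL3 (-5.57, SE 0.30), osteopontin (SPP1, -5.63, SE 0.26), the heparan sulfate proteoglycan SDC2 (-5.23), the fatty acid carrier FABP4 (-5.18) and the membrane protein TMEM158 (-5.12). The highest adjusted p among the 25 genes was 3.0e-04, for TNFSF10, and each of them moved the same way in all 3 pairs. Leaving out 1 pair moved some folds by more than 1.5 times. Without pair 1 the log2 values were 5.34 for HERC5, 5.07 for RSAD2, 4.74 for CXCL10, 4.04 for IFIT1, 4.38 for ISG15, 4.11 for LY6E, 4.09 for DHX58 and 3.64 for TNFSF10. Without pair 3 they were 6.42 for CXCL10, 6.10 for IFIT1, 5.63 for ISG15, 5.70 for TNFSF10 and -7.15 for SCG5.

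**Figure D1:**
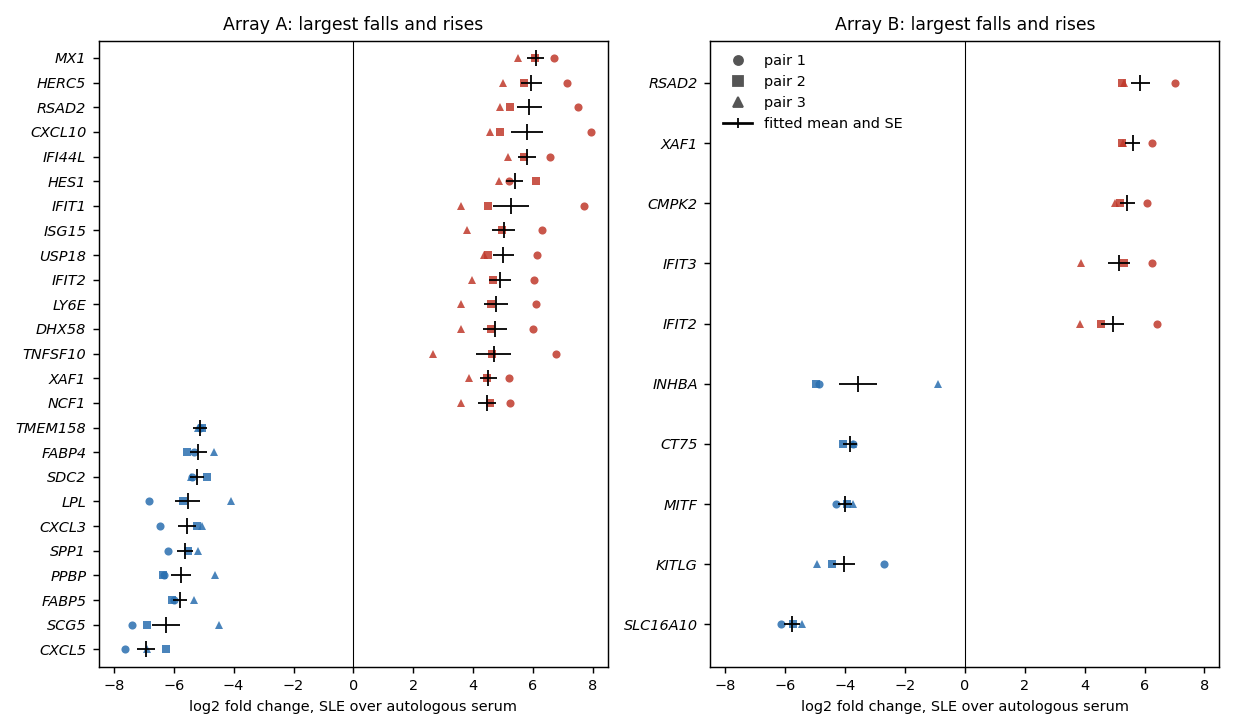
Log2 fold change of SLE over autologous serum on the log2(signal + pseudocount) scale for the genes of the largest rises and falls on array A (left) and array B (right), where colored points are the 3 pairs and the black cross with its bar is the fitted mean and its SE. MX1 rose by 6.08 and CXCL5 fell by 6.92 on the log2 scale on array A, and INHBA on array B lay at -4.88, -4.96 and -0.89 in pairs 1, 2 and 3.

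Over all of array A, 11487 probe sets passed the filter and 3546 of them (30.9%) changed at a limma adjusted p under 0.05, of which 1634 rose, 1912 fell and 3536 moved the same way in all 3 pairs. A rise of at least 4-fold was seen for 302 of the changed probe sets and a fall of that size for 244. Array B gave 1790 changed probe sets of 11820 (15.1%), with 847 that rose and 943 that fell. Counted as genes, 1009 rose and 1220 fell of 6973 on array A, and 482 rose and 563 fell of 6032 on array B. Without pair 2 the counts were 2241 on array A and 628 on array B, and without an intensity trend in the variance array B gave 986. Of 26 gene lists tested on array A with limma's camera, 11 were called (9 upward and 2 downward), and of 10 on array B 4 were called, all upward. With an estimated correlation 0 were called on either array (1 and 0 at an unadjusted p under 0.05), and with fry 3 and 2. Among splits of the 6 arrays that mix the sera, up to 10 lists were called on array A and up to 3 on array B. The 3'/5' signal ratio of the ACTB control probe sets, a measure of RNA and labelling quality, lay between 5.76 and 12.1 on array A with autologous serum and between 10.2 and 14.1 with SLE serum. For GAPDH the ranges were 2.06 to 2.95 and 2.04 to 4.30. With SLE serum the ACTB ratio of array A was 2.31, 1.42 and 0.841 times that with autologous serum in pairs 1, 2 and 3. The pair medians of 10 of the 26 lists tested on array A followed that order in size and those of 5 the opposite order; among the 11 called lists these numbers were 6 and 1. On array B they were 3 and 2 of 10, and 0 and 1 of the 4 called.

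**Figure D2:**
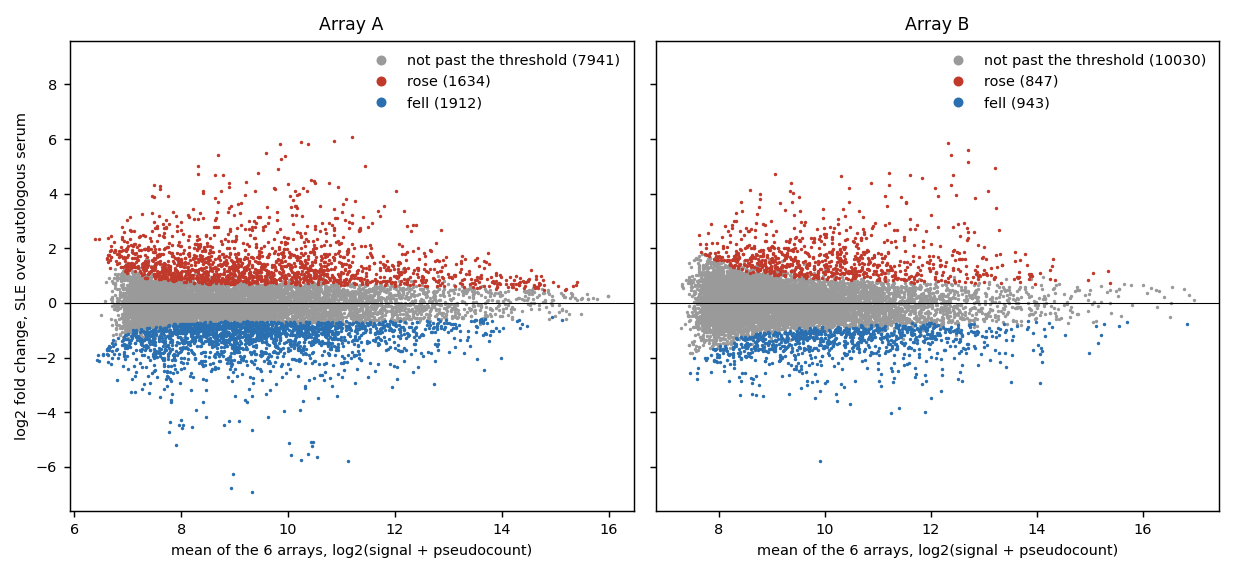
Each point is a probe set that passed the filter on array A (left) or array B (right), by its mean over the 6 arrays on the log2(signal + pseudocount) scale and its log2 fold change of SLE over autologous serum. On array A 1634 probe sets rose and 1912 fell, and on array B 847 rose and 943 fell, with the rest not past an adjusted p of 0.05.

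Of 47 measured interferon-stimulated genes on array A, 46 rose and 0 fell (47 and 0 when adjusted over the list alone, and also at an unadjusted limma p under 0.05), with a median log2 change of 3.70. MX1, IFI44L, HERC5 and XAF1 had the smallest p-values, and pair medians were 4.79, 3.50 and 2.96 in pairs 1, 2 and 3, in the order of the pairs' 3'/5' ratios. The camera test gave an adjusted p of 5.9e-36 with the preset correlation between genes, and an adjusted p = 0.514 with an estimated correlation. With fry the adjusted p was 0.0620, so this list was not among those that fry called on array A. SIGLEC1, an adhesion receptor of monocytes and macrophages that interferon induces, rose from 112.4 to 1900.4 (log2 3.46, SE 0.41, limma adjusted p = 2.5e-04; log2 2.69 without pair 1). Genes typical of interferon gamma followed: 11 of 14 rose and 0 fell, the same when adjusted over the list alone and at an unadjusted p under 0.05, with a median of 1.64 (camera adjusted p = 6.1e-07; adjusted p = 0.514 with an estimated correlation). Among these were the aminopeptidase LAP3 (log2 3.37), CXCL10 (5.80), the lymphocyte-type receptor SLAMF7 (2.25) and the transcription factor IRF1 (1.88). Of 18 members of the interferon receptor and JAK-STAT list, 4 rose and 1 fell (the same when adjusted over the list alone), and the list was not called (median 0.13, camera adjusted p = 0.529). JAK2, a kinase of cytokine receptors, rose by 2.70 (SE 0.27, limma adjusted p = 9.2e-05). The other 4 calls, IFNGR2 (1.05), STAT5A (0.94), IFNGR1 (0.63) and STAT4 (-0.87), ended without pair 2, where their adjusted p-values were 0.0625, 0.0729, 0.330 and 0.290; STAT5A also ended without pair 3 (0.0819). The probe set of IFNGR1 on array B lay the other way, at a log2 value of -0.74 (limma adjusted p = 0.0798; log2 -0.96 and adjusted p = 0.0426 without pair 3). The interferon genes themselves were near the floor: IFNA17 had mean signals of 168.3 and 103.2 with autologous and SLE serum (limma adjusted p = 0.258). IFNG had mean signals of 121.9 and 124.6 (limma adjusted p = 0.965), and no other of the 16 listed interferon genes had a probe set past the filter. Neither of the pair passed at an unadjusted p under 0.05.

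Antigen processing genes were among those that rose. PSMB9, a subunit of the immunoproteasome, rose from 468.4 to 3858 (log2 2.80, SE 0.34, limma adjusted p = 2.8e-04), the peptide transporter TAP1 by 2.41 (SE 0.35; 1.82 without pair 1), PSMB10 by 2.09 and the proteasome activator PSME1 by 1.37. In the list of MHC class I and immunoproteasome genes, 7 of 14 rose and 0 fell, the same when adjusted over the list alone (8 and 0 at an unadjusted p under 0.05), with a median of 0.58 (camera adjusted p = 1.8e-04; adjusted p = 0.514 with an estimated correlation). Pair medians were 1.13, 0.64 and 0.22 for this list and 0.69, 0.52 and 0.05 for MHC class II genes, in the order of the pairs' 3'/5' ratios. Of 12 MHC class II genes, 2 rose and 0 fell, also when adjusted over the list alone (4 and 0 at an unadjusted p under 0.05), and the risen pair encodes lysosomal proteases that prepare antigen: CTSH rose by 1.91 (SE 0.21, limma adjusted p = 1.9e-04) and CTSS by 1.39 (SE 0.20, adjusted p = 8.3e-04). HLA-DRA, a chain of the class II molecule itself, had mean signals of 18402 and 16350.4 (log2 -0.18, adjusted p = 0.489). HLA-DQA1 (log2 0.65) and CD74 did not pass in the main fit. HLA-DQA1 passed with no replicate block (limma adjusted p = 0.0459) and after quantile normalization (0.0372). CD74 passed without pair 1 (log2 0.73, limma adjusted p = 0.0133) and without pair 3 (log2 1.30, 0.00676). The class II list had a median of 0.33 and a camera adjusted p of 0.0427 (adjusted p = 0.514 with an estimated correlation); its adjusted p was 0.0661 without pair 1 and 0.138 without pair 2. It was 0.121 after quantile normalization, 0.0586 with a filter at the 75th percentile and 0.0540 without an intensity trend.

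Of 17 genes of dendritic cell maturation 7 rose and 1 fell. LAMP3, a lysosomal protein of mature dendritic cells, rose from 85.7 to 1159 (log2 3.11, SE 0.41, limma adjusted p = 4.4e-04). CCR7, the receptor that guides cells to lymph nodes, rose from 102.7 to 792.4 (log2 2.46, SE 0.37, adjusted p = 9.6e-04), and the T and NK cell growth factor IL15 and its receptor IL15RA by 3.06 and 2.79. Without pair 1 the log2 values were 2.37 for LAMP3, 1.82 for CCR7 and 2.13 for IL15RA. CCL22, a chemokine of dendritic cells and macrophages, fell from 600.5 to 42.8 (log2 -3.02, SE 0.29, adjusted p = 8.4e-05). The costimulatory ligand CD80 rose by 1.07 (SE 0.33, adjusted p = 0.0307), with adjusted p-values of 0.0641 without pair 1 and 0.113 without pair 3. CD83, CD86 and CD40 did not pass, with log2 values of -0.43, -0.19 and -0.16 and adjusted p-values of 0.201, 0.625 and 0.641. The counts were the same when adjusted over the list alone, and the list was not called (median 0.14, camera adjusted p = 0.0547). Without pair 2 its adjusted p was 3.1e-04, after quantile normalization 0.0469, and with the mean of a gene's probe sets 0.0499. CLEC10A, a lectin used as a marker of conventional dendritic cells, rose from 118.0 to 815.4 (log2 2.50, limma adjusted p = 1.2e-04). In the same marker list FLT3 had a log2 value of 0.10 (limma adjusted p = 0.831), and CD1C (-1.14), FCER1A (1.37), CADM1 (0.72) and XCR1 (0.05) did not pass the filter.

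Of 14 chemokines outside the interferon lists, 9 fell and 2 rose. Besides CXCL5, PPBP and CXCL3, CXCL1 fell from 8198 to 204.2 (log2 -5.10, SE 0.23, limma adjusted p = 1.2e-06), and CCL2, the main monocyte attractant, from 9388 to 1482 (log2 -2.70, SE 0.31, adjusted p = 2.1e-04). The counts were the same when adjusted over the list alone, and the list had a median of -2.19 (camera adjusted p = 3.4e-04; adjusted p = 0.514 with an estimated correlation). The 2 that rose were CCL4 (log2 1.41, SE 0.24) and CCL8 (2.79, SE 0.77; adjusted p = 0.0828 without a filter, and log2 1.21 without pair 1 and 4.03 without pair 3), both attractants of monocytes and lymphocytes. CXCL8 (interleukin 8) had mean signals of 29108 and 29251 (log2 0.05, adjusted p = 0.871) on its brightest probe set, while its other probe set fell from 4312 to 1029 (limma adjusted p = 3.0e-04). PPBP is also a platelet marker, and GNG11, another platelet marker, fell from 704 to 49.0 (log2 -3.34, adjusted p = 3.0e-04; log2 -4.04 without pair 1).

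Inflammatory cytokines went both ways. EREG, a growth factor of the EGF family, fell by 3.95 on the log2 scale (SE 0.23, limma adjusted p = 4.8e-06), the activin subunit INHBA by 4.46 (SE 0.49), the interleukin 1 receptor antagonist IL1RN by 2.46 (SE 0.35) and the macrophage growth factor CSF1 by 3.54 (SE 0.50). Without pair 1 the log2 values were -3.71 for INHBA, -3.12 for IL1RN and -2.80 for CSF1, and without pair 3 -5.33 for INHBA and -4.50 for CSF1. IL6 rose from 76.4 to 480.2 (log2 2.13, SE 0.30, adjusted p = 6.7e-04) and the interleukin 23 subunit IL23A from 37.5 to 184 (log2 1.71, SE 0.40). IL1B had mean signals of 23684 and 15238 (log2 -0.60, SE 0.23, adjusted p = 0.0675) and TNF of 711.5 and 1066 (log2 0.58, SE 0.24, adjusted p = 0.101). Quantile normalization took IL1B to an adjusted p of 0.0305, and leaving out pair 1 took TNF to 0.0430. Of the 10 measured cytokines, 2 rose and 4 fell (2 and 5 when adjusted over the list alone). The list was not called (median -0.70, camera adjusted p = 0.215), with pair medians of -1.20, -0.63 and -0.18 in the order of the 3'/5' ratios. Its camera adjusted p was 0.00183, 0.00276 and 0.0447 without pair 1, 2 and 3. Without pairs 1 and 2 the variance was largely pooled over probe sets (11487 and 74.4 degrees of freedom, against 10.1 with all pairs). Lower values there say little about stability.

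Of 17 NF-kB targets and regulators 9 rose and 0 fell (10 and 0 when adjusted over the list alone and at an unadjusted p under 0.05), with a median of 0.80 (camera adjusted p = 2.4e-04; adjusted p = 0.514 with an estimated correlation). GCH1, the first enzyme of tetrahydrobiopterin synthesis, rose by 2.18 (SE 0.21, limma adjusted p = 7.0e-05), TNFAIP2 by 2.01 and the hyaluronan-binding protein TNFAIP6 by 1.89. Among pattern recognition genes, the DNA sensor IFI16 rose by 3.33 (SE 0.24), TLR7, which senses single-stranded RNA, from 12.8 to 388.3 (log2 3.16, SE 0.38), the adaptor MYD88 by 1.91 and the muramyl dipeptide sensor NOD2 by 2.37. The 3 members that fell were the Toll-like receptors TLR4 (-1.81, SE 0.28), TLR2 (-1.04, SE 0.18) and TLR1 (-0.85, SE 0.23; adjusted p = 0.169 without pair 2). The list held 12 members that rose and 3 that fell of 18, the same when adjusted over the list alone, with a median of 1.18 (camera adjusted p = 0.00134; adjusted p = 0.514 with an estimated correlation; 0.0586 with a filter at the 75th percentile). Its pair medians, 1.60, 0.94 and 0.61, followed the 3'/5' ratios. In the list of TNF family ligands and apoptosis genes, 6 of 18 rose and 2 fell, the same when adjusted over the list alone. TNFSF13 (APRIL), a B cell growth factor, rose by 2.76 (SE 0.28) and TNFSF10 by 4.68 (3.64 without pair 1 and 5.70 without pair 3), while the survival genes BCL2L1 and MCL1 fell by 1.59 and 0.74 on the log2 scale, MCL1 not without pair 2 (adjusted p = 0.155). This list was not called (median 0.28, camera adjusted p = 0.150; 0.0436 without pair 2). On array B, TNFSF13B (BAFF), a survival factor of B cells, rose from 2845 to 32565 (log2 3.48, SE 0.26, adjusted p = 1.5e-05).

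Genes of the monocyte itself moved in both directions. The proteoglycan VCAN fell from 24494 to 6149 (log2 -2.05, SE 0.20, limma adjusted p = 9.6e-05), the scavenger receptor CD36 by 2.43 on the log2 scale (SE 0.25) and CD93 by 1.63, whereas MS4A6A rose by 2.16 (SE 0.27) and the fractalkine receptor CX3CR1 by 2.08 (SE 0.38). The lipopolysaccharide coreceptor CD14 fell from 8684.5 to 4398 (log2 -0.96, SE 0.25, adjusted p = 0.0165; 0.0912 without pair 3). In the list of classical monocyte genes, 5 of 17 members rose and 5 fell (6 and 5 when adjusted over the list alone). Its members, CX3CR1 and CSF1R among them, need not mark classical monocytes alone, so the counts do not describe that subset. The list had a median of -0.22, a mean of -0.01 and an upward camera test at an adjusted p of 0.905, so that the signs differed. FPR1 (1.36), FCN1 (1.04) and CSF3R (0.97) completed the rises and CSF1R (-0.90) the falls, with CSF3R at an adjusted p of 0.101 without pair 2 and CSF1R at 0.0540 and 0.0739 without pairs 1 and 3. Among macrophage and scavenger receptor genes, SPP1 and FABP4 fell, as did the mannose receptor MRC1 (-2.95, SE 0.47; -2.29 without pair 1 and -3.70 without pair 3) and the hemoglobin scavenger CD163 (-2.12, SE 0.35; -1.53 without pair 3). GPNMB (1.37), STAB1 (0.81) and F13A1 (0.97) rose, but STAB1 and F13A1 were at adjusted p-values of 0.231 and 0.330 without pair 2. That gave 3 rises and 4 falls in 15 (3 and 5 when adjusted over the list alone) and no call (median -0.27, camera adjusted p = 0.222; 0.00371 without pair 1 and 0.00641 without pair 2). The fry test, which asks whether a list's genes move 1 way and, like its mixed version, compares no list with other genes, gave an adjusted p of 0.0176 for this list.

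Of 14 cholesterol synthesis genes 5 rose and 0 fell, the same when adjusted over the list alone (8 and 0 at an unadjusted p under 0.05): EBP (1.15, SE 0.25), SC5D (0.98), DHCR7 (1.55) and LSS (1.33), enzymes of the pathway, and SREBF2 (0.89), its transcription factor. The list had a median of 0.63 and a camera adjusted p of 0.0245 (adjusted p = 0.514 with an estimated correlation), 0.0865 and 0.137 without pairs 2 and 3, and 0.120 with a filter at the 75th percentile. All of these calls but that of EBP ended without pair 2, at adjusted p-values of 0.0653 for SC5D, 0.0726 for DHCR7, 0.203 for LSS and 0.150 for SREBF2. Without pair 1 they were 0.0622 for LSS and 0.0547 for SREBF2, and without pair 3 0.0602 for SC5D. The log2 value of LSS was 1.93 without pair 3. Without pair 2 the log2 values were 1.04 for SC5D, 1.43 for DHCR7, 0.89 for LSS and 0.80 for SREBF2. That of SC5D was thus not smaller than with all pairs. In the LXR and PPAR lipid list, the cholesterol exporter ABCG1 (1.85, SE 0.28) and the transcription factor SREBF1 (1.45, SE 0.35) rose, and FABP5, FABP4 and LPL fell, 2 and 3 of 12 members, the same when adjusted over the list alone. Its median was 0.26, its mean -0.91 and its camera test downward at an adjusted p of 0.688 (0.00685 without pair 1 and 0.0195 without pair 2), so that the signs differed.

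**Figure D3:**
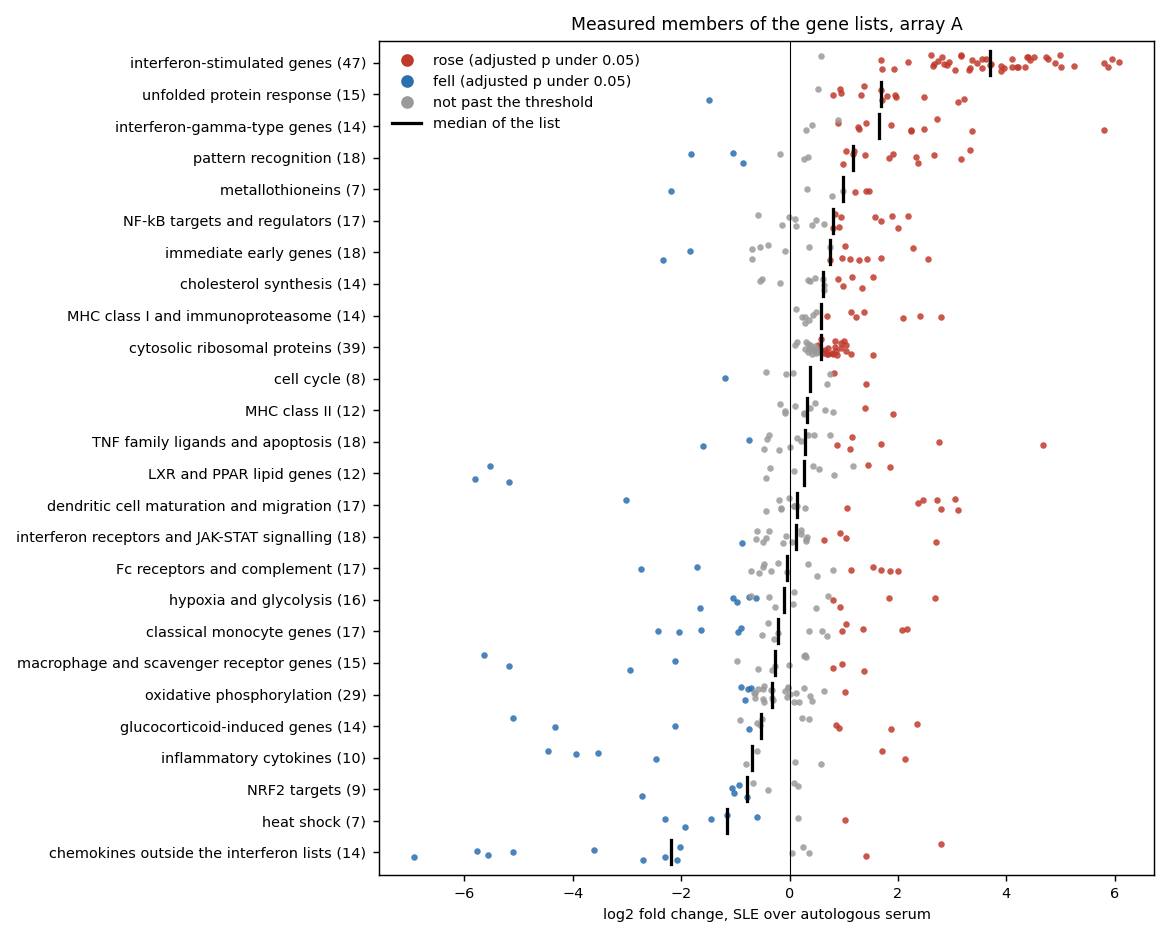
Log2 fold change of SLE over autologous serum for the measured members of each gene list on array A, with the number of members in parentheses, colored by whether the member passed an adjusted p of 0.05, and with a black bar at the list's median. The medians ran from -2.19 for chemokines outside the interferon lists to 3.70 for interferon-stimulated genes.

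Of 15 genes of the unfolded protein response, which restores protein folding in the endoplasmic reticulum, 13 rose and 1 fell, the same when adjusted over the list alone. The median was 1.70 (camera adjusted p = 6.6e-08; adjusted p = 0.514 with an estimated correlation). SDF2L1, a chaperone component, rose from 323.3 to 3314 (log2 3.23, SE 0.23, limma adjusted p = 1.4e-05). The stress transcription factor DDIT3 (CHOP) rose from 616.5 to 5566 (log2 3.11, SE 0.24, adjusted p = 1.8e-05), HERPUD1 by 1.95 (SE 0.20) and the chaperone partner DNAJB9 from 2486 to 8727 (SE 0.21). The member that fell was ASNS, the asparagine synthetase (-1.49, SE 0.26). Pair medians were 1.34, 1.46 and 1.82, and the fry adjusted p was 0.0167. Among heat shock genes of the cytosol and mitochondria, HSPD1 (-2.30, SE 0.22), HSP90AB1 (-1.93, SE 0.35), HSPH1 (-1.45, SE 0.27), HSPE1 (-1.15, SE 0.27) and HSP90AA1 (-0.61, SE 0.17) fell, and the cochaperone BAG3 rose (1.02, SE 0.24). HSP90AA1 and BAG3 were at adjusted p-values of 0.212 and 0.0675 without pair 2. These were 5 falls and 1 rise among 7 members, the same when adjusted over the list alone, and the list was not called (median -1.15, camera adjusted p = 0.0579), with pair medians of -1.65, -1.20 and -0.59 in the order of the 3'/5' ratios. Its adjusted p-values were 0.0393 without pair 1, 0.0224 without pair 3, 0.0449 after quantile normalization and 0.0113 without a filter. NRF2 targets, which protect from oxidants, fell in 5 of 9 cases and rose in 0 (6 and 0 when adjusted over the list alone and at an unadjusted p under 0.05), led by malic enzyme ME1 (-2.72, SE 0.24) and thioredoxin reductase TXNRD1 (-0.92, SE 0.18). Thioredoxin (TXN, -1.07), NQO1 (-1.02) and SLC7A11 (-0.78) also fell, but not without pair 2 (adjusted p = 0.121, 0.0696 and 0.0683). The list had a median of -0.78, a camera adjusted p of 0.0151 (adjusted p = 0.514 with an estimated correlation) and a fry adjusted p of 0.00232, with pair medians of -0.89, -0.85 and -0.71 that followed the 3'/5' ratios in size.

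Among cytosolic ribosomal protein genes the rises were small, with RPS14 at 1.55 (SE 0.22, limma adjusted p = 7.0e-04) and RPL32 at 1.04 (SE 0.20, adjusted p = 0.00367). Of 39 members on array A 23 rose and 0 fell (27 and 0 when adjusted over the list alone, 28 and 0 at an unadjusted p under 0.05), with a median of 0.57 (camera adjusted p = 1.0e-08; adjusted p = 0.514 with an estimated correlation). Pair medians were 0.78, 0.67 and 0.33, in the order of the 3'/5' ratios. The number that rose was 14 after quantile normalization and 25 after scaling to a common median. On array B, RPL11 (0.87) and RPL19 (1.09) rose and 0 of 22 members fell, also when adjusted over the list alone (11 and 0 at an unadjusted p under 0.05). Their adjusted p-values were 0.249 and 0.323 without pair 2, and 0.0642 and 0.0516 after scaling to a common median. The list had a median of 0.47 and a camera adjusted p of 0.00205 there (adjusted p = 0.539 with an estimated correlation). Immediate early genes, which answer growth and stress signals within minutes, held 9 rises and 2 falls in 18 (10 and 3 when adjusted over the list alone). KLF4 rose by 2.55 (SE 0.25) and ZFP36, which destabilizes cytokine mRNA, by 1.68 (SE 0.26), while JUN fell by 1.84 and MYC by 2.34 on the log2 scale. The list was not called (median 0.75, camera adjusted p = 0.0742; 0.00785 without pair 1 and 0.0429 with a filter at the 75th percentile). Of 7 genes in the metallothionein list, 3 rose and 1 fell (4 and 1 when adjusted over the list alone). The metal-binding proteins MT1E (1.40), MT1H (1.47; 0.85 without pair 1) and MT1G (1.21; adjusted p = 0.0507 without pair 1) rose, and the zinc exporter SLC30A1 fell by 2.18 on the log2 scale (SE 0.23). That list was not called (median 0.98, camera adjusted p = 0.138; 0.0401 without pair 3), and its pair medians were 2.16, 0.91 and -0.09, in size in the order of the 3'/5' ratios.

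Metabolic and regulatory lists had members on both sides and no call. In hypoxia and glycolysis, 4 of 16 rose and 5 fell (5 and 5 when adjusted over the list alone). NDRG1 rose by 2.69 (SE 0.31) and the angiogenic factor VEGFA by 1.84 (SE 0.32), and the glucose transporter SLC2A3 fell by 1.66 and the glycolytic enzyme ENO1 by 1.04 on the log2 scale. SLC2A1 (0.93) and HK2 (0.80) also rose, and PGK1 (-0.62), TPI1 (-0.74) and PKM (-0.97) fell. Without pair 2 SLC2A1, HK2, PGK1 and TPI1 were at adjusted p-values of 0.0794, 0.299, 0.285 and 0.276, and PKM was at 0.0993 without pair 1. SLC2A1, HK2 and PKM were at 0.0562, 0.0704 and 0.0859 without pair 3. Without a filter ENO1, SLC2A1, PGK1 and PKM were at limma adjusted p-values of 0.0659, 0.0753, 0.102 and 0.0797. The list had a median of -0.10, a mean of 0.08 and an upward camera test (adjusted p = 0.905), so that signs differed. Of 29 oxidative phosphorylation genes, COX4I1 rose (1.03, SE 0.22), and the respiratory chain subunits NDUFB3 (-0.83), NDUFA1 (-0.77), COX7B (-0.90) and SDHC (-0.71) fell, with 1 rise and 0 falls when adjusted over the list alone (2 and 7 at an unadjusted p under 0.05). These 4 falls ended without pair 2 (adjusted p = 0.134, 0.254, 0.201 and 0.151) and without pair 3 (0.0553, 0.130, 0.166 and 0.104), and that of SDHC without pair 1 (0.0734). The list had a median of -0.32 (camera adjusted p = 0.291). Glucocorticoid-induced genes, which mark steroid exposure, showed 4 rises and 4 falls in 14 (4 and 6 when adjusted over the list alone). TSC22D3 rose by 2.34 (SE 0.24), DDIT4 by 1.88 (SE 0.23), NFKBIA by 0.91 and SGK1 by 0.86, and the decoy receptor IL1R2 (-5.11, SE 0.29), thrombomodulin (THBD, -4.32, SE 0.28), CD163 and THBS1 (-0.75) fell. SGK1 was at an adjusted p of 0.222 without pair 3, and THBS1 at 0.173 and 0.0968 without pairs 2 and 3. The list was not called (median -0.52, camera adjusted p = 0.547; 0.0217 without pair 1), and FKBP5, measured on array B, had mean signals of 7751 and 12336 (log2 0.65, limma adjusted p = 0.0634; 0.0488 without pair 1 and 0.0466 with a filter at the 75th percentile).

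Fc receptor and complement genes held 5 rises and 2 falls in 17 (5 and 3 when adjusted over the list alone). Properdin (CFP, 1.85, SE 0.28), C3 (1.69, SE 0.29), FCGR2A (1.13, SE 0.26) and the C1 inhibitor SERPING1 (1.55, SE 0.50) rose. FCGR1BP rose from 123.8 to 629.6 (SE 0.36), and the complement regulator CD59 (-2.75, SE 0.31) and the C5a receptor C5AR1 (-1.71, SE 0.26) fell. FCGR1BP is a near-identical copy of the IgG receptor gene FCGR1A, whose own probe set did not pass the filter, so the source of its signal is uncertain, and SERPING1 was at log2 0.60 and an adjusted p of 0.302 without pair 1 and at log2 2.15 without pair 3. The list had a median of -0.05, a mean of 0.15, pair medians of 0.26, 0.21 and -0.09 (in size in the order of the 3'/5' ratios) and a camera adjusted p of 0.566, so that the signs differed. Of 8 measured cell cycle genes, the replication helicase subunits MCM2 (1.42, SE 0.31) and MCM5 (0.82, SE 0.28) rose and the mitotic kinase AURKA fell (-1.19, SE 0.32), or 4 rises and 1 fall when adjusted over the list alone. MCM5 was at an adjusted p of 0.456 without pair 2, and AURKA at 0.0632 and 0.0644 without pairs 1 and 2. That list was not called (median 0.37, camera adjusted p = 0.346). IL10, which restrains inflammation, had mean signals of 75.7 and 74.5 and did not pass the filter.

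Array B carries other probe sets, and its largest rises were again interferon-stimulated genes. RSAD2 rose by 5.86 (SE 0.33, limma adjusted p = 4.6e-06), XAF1 from 907 to 47241 (SE 0.25), the nucleotide kinase CMPK2 from 762.3 to 35076.5 (log2 5.42, SE 0.26), IFIT3 by 5.15 and IFIT2 by 4.93. The largest falls were SLC16A10, a transporter of aromatic amino acids, from 7337 to 67.3 (log2 -5.78, SE 0.28, adjusted p = 1.3e-06), KITLG, the ligand of the KIT receptor (-4.03, SE 0.37), the transcription factor MITF (-3.99, SE 0.23), the non-coding transcript CT75 (-3.85, SE 0.23) and INHBA (-3.57, SE 0.63). Without pair 1 the log2 values were 4.19 for IFIT2, -4.69 for KITLG, -2.92 for INHBA and 2.92 for the list member GBP4. Without pair 3 they were 5.78 for IFIT3, -4.92 for INHBA and 4.82 for GBP4, and without pair 2 INHBA was at -2.88. CT75 was read by a pair of probe sets, 1 of which fell. Of 18 measured interferon-stimulated genes on array B 18 rose and 0 fell, also when adjusted over the list alone and at an unadjusted p under 0.05, with pair medians of 4.54, 3.78 and 3.86 (camera adjusted p = 2.6e-25; adjusted p = 0.465 with an estimated correlation). Interferon-gamma-type genes held 8 rises and 0 falls in 11 (11 and 0 when adjusted over the list alone and at an unadjusted p under 0.05), among them GBP3 (3.38) and GBP4 (3.89), guanylate-binding proteins, with a median of 1.95 (camera adjusted p = 7.8e-09; adjusted p = 0.465 with an estimated correlation). In the NF-kB list 3 of 6 rose and 0 fell, also when adjusted over the list alone and at an unadjusted p under 0.05. NFKBIZ rose from 7527 to 26713 (SE 0.22), and the others were TNIP1 (1.85, SE 0.29) and NFKBIA (1.30, SE 0.34; adjusted p = 0.215 and 0.0517 without pairs 2 and 3). Its median was 0.87 and its camera adjusted p 0.0390, with an adjusted p = 0.465 with an estimated correlation and 0.102 without pair 3. The 4th list called on array B was that of ribosomal proteins, and the other 6 tested lists were not called. Pattern recognition had a camera adjusted p of 0.0657 (0.0467 without pair 2, 0.0390 after scaling to a common median and 0.0399 with a filter at the 75th percentile), TNF family and apoptosis genes 0.169, dendritic cell maturation 0.541 and oxidative phosphorylation 0.785. On array B the glucocorticoid list had a median of 0.36, a mean of -0.30 and a downward camera test (adjusted p = 0.785), and the JAK-STAT list a median of -0.43, a mean of 0.17 and a downward test (adjusted p = 0.788), so that signs differed in both.

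**Figure D4:**
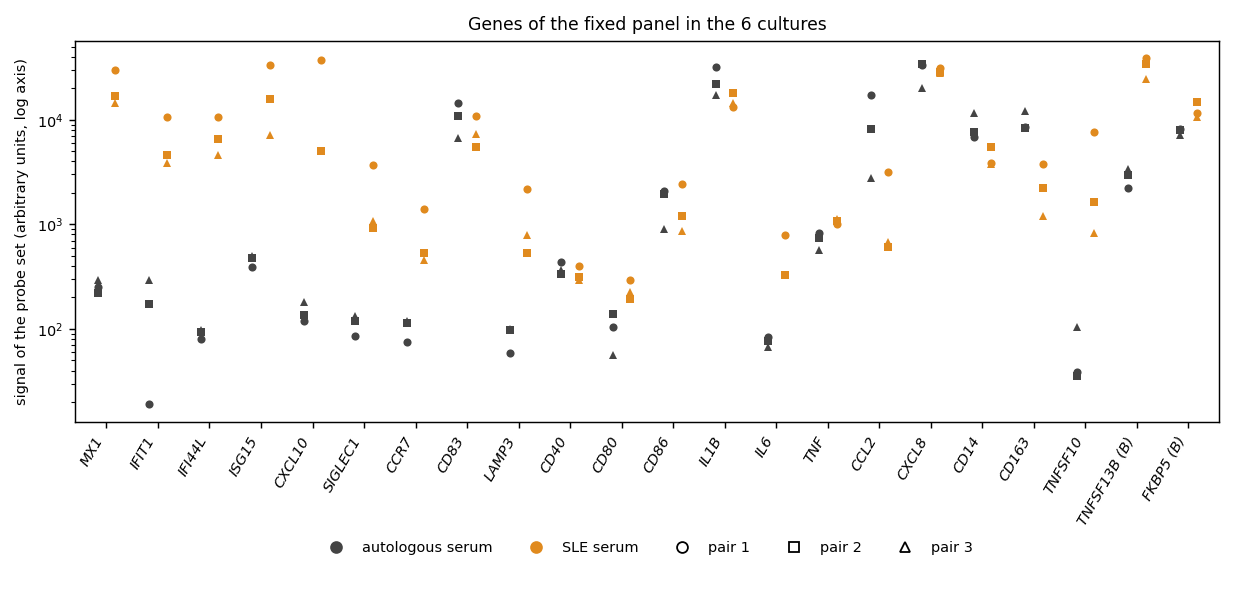
Signal of the probe set used for genes chosen before the data were examined, on a log axis in arbitrary units, in the 3 cultures with autologous serum and the 3 with SLE serum, with a symbol for each pair and genes read on array B marked (B). HLA-DRA is not drawn; mean signals of MX1 were 256 and 20405, those of CXCL8 29108 and 29251, and those of CD14 8684.5 and 4398.

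Markers of other blood cells were read as levels on array A. Median signals with autologous and SLE serum were 89.6 and 80.9 for T cell markers, 91.0 and 94.4 for B cell markers, 59.5 and 58.9 for NK cell markers, 25.3 and 33.2 for plasma cell markers, 68.4 and 38.9 for neutrophil markers and 113.3 and 71.0 for erythroid markers, against a filter level of 113. Platelet markers had medians of 97.5 and 83.6, plasmacytoid dendritic cell markers of 358.7 and 448.9, and conventional dendritic cell markers of 98.4 and 136.7. Single markers lay well above the filter level with autologous serum, among them PPBP (9764), IL3RA (1370) and FCGR3B (530.6). Besides PPBP, GNG11 and CLEC10A, 4 markers changed. TCF4 (log2 1.32, limma adjusted p = 0.0233; log2 0.70 and adjusted p = 0.0598 without pair 1) and FCGR3B (1.11, adjusted p = 0.00925), whose probe set can also read the close copy FCGR3A, rose, and IL3RA (-1.41, adjusted p = 0.00313) and the protease GZMB (-1.72, adjusted p = 0.00659) fell.

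Across the 11487 probe sets of array A, the log2 changes of pairs 1 and 2 correlated with r = 0.80 (rho 0.73), those of pairs 1 and 3 with r = 0.68 (rho 0.59) and those of pairs 2 and 3 with r = 0.74 (rho 0.66); these are correlations across probe sets, which are not independent replicates. On array B the values of r were 0.59, 0.47 and 0.50. At least 2-fold higher with SLE serum in each of the 3 pairs were 645 probe sets on array A and 479 on array B, and 624 and 388 were at least 2-fold lower. With the sign of pair 1, 2 or 3 flipped, 4, 1 and 5 probe sets of array A met the same criterion in either direction, against 1269 as labelled, and 25, 27 and 44 of array B, against 867. Without pair 3, 981 were higher and 1034 lower in the pairs left on array A, and 813 and 742 on array B, where 592 were lower without pair 2. Over all samples of array A, correlations of log2 signals between arrays of the same serum lay between 0.934 and 0.971, and between arrays of different serum between 0.776 and 0.857.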

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

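The tests of 3' bias behind the rise and fall of transcripts and of platelets behind the fall of chemokines were chosen only after the results they bear on had been seen.

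The control probe sets of the arrays, which the comparison of sera left out, held signals of ribosomal RNA that were higher on every SLE serum array than on every autologous array, on both array types (3 against 3 separate completely in 10% of cases by chance). The 28S ribosomal RNA controls were higher with SLE serum by log2 1.60 on array A (SD 0.52 over 3 pairs) and 1.65 on array B (SD 0.55), or 1.27 and 1.47 relative to the hybridization spike controls. The 18S ribosomal RNA controls were higher by 0.75 on array A (SD 0.42) and 0.72 on array B (SD 0.33), or 0.42 and 0.54 relative to the spike controls. In pairs 1, 2 and 3 the 28S values were 2.13, 1.57 and 1.09 on array A and 2.29, 1.41 and 1.26 on array B, in the order of the pairs' 3'/5' ratios. The 18S values did not follow that order, at 1.19, 0.37 and 0.70 on array A and 1.06, 0.40 and 0.70 on array B. Those of the ACTB controls did in size (-2.10, -0.95 and -0.32 on array A), but these controls include the probe sets that give the ACTB ratio. The spike controls, added to each sample, were themselves higher by 0.33 on array A and 0.18 on array B, and the ACTB controls lay at -1.13 (SD 0.90) and -1.26 (SD 0.90). On array A the spike controls, too, were higher on every SLE serum array than on every autologous array. Complete separation there is thus not particular to ribosomal RNA. Both array types hold the same RNA, so array B is not a second set of cultures.

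The rise and fall of transcripts across the arrays was set against a loss of the 5' ends of the RNA on the SLE serum arrays, which could change signals without a change in transcript number. On array A the 3'/5' ratio with SLE serum was 2.31, 1.42 and 0.841 times that with autologous serum for ACTB in pairs 1, 2 and 3, and 2.09, 1.54 and 0.691 times for GAPDH. In pair 3, where neither ratio was higher, 92.8% of the 3330 probe sets called from pairs 1 and 2 moved the same way (95% interval from 91.9%, counting error only, as probe sets are not independent), and 90.8% did on array B, which argues against 3' bias as the whole cause, although it rests on 1 pair. A share in the size of the changes stays open, as the probe sets called from the other pairs had median log2 changes of 0.99 for rises and -0.92 for falls in pair 3, against 1.30 and -1.38 in pair 1. SLE serum itself, the biological explanation that the design names, also stays open, and cannot be parted here from an effect of serum of another person.

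The fall of CXC chemokines, among them the platelet marker PPBP, was set against platelets carried into the autologous serum cultures, which could bring PPBP and GNG11. Platelets would bring their other abundant transcripts into those cultures too, but the 7 platelet markers other than PPBP, with GNG11 among them, had a median signal of 91.1 there (spread of the median 15.2), below the filter level of 113, with PF4 at 84.9 and TUBB1 at 57.8, which argues against platelets as the whole cause. The log2 changes of these 7, a test chosen first, had a median of -0.090 (spread of the median 0.18) and did not decide, as 4 of them lay below the filter, PF4 at -0.92 among them. GNG11 fell by 3.34 on the log2 scale, so platelet RNA as the source of a part of the fall stays open. The biological explanation, an effect of SLE serum on monocytes, was not tested further.

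Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. A split that mixes the sera leaves much of the serum difference in its residual spread. A low count of changed probe sets there was thus built in and does not measure chance. With 3546 changed probe sets on array A and 1790 on array B, 1 of the 10 splits, the real one, gave as many on each array type, and the highest count of any other split was 0 on both (limma; 678 and 769 at an unadjusted p under 0.05, against 4825 and 3246). For gene lists, 1 of the 10 splits gave as many as the 11 called on array A, and 1 as many as the 4 on array B. The highest other split gave 10 lists on array A and 3 on array B, and 9 and 3 among the 3 other splits that part all 3 pairs. The remaining 6 part only 1 pair, and with the pair as a block each of them has the same counts as another of the 6.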

How the results depend on the processing

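Counting genes in place of probe sets was chosen only after the result was seen; the other alternatives were planned. No result changed direction among those past the threshold under any alternative that was run. Changed probe sets on array A numbered 3546 and ranged from 2594 without a filter to 3847 with no replicate block, apart from 2241 without pair 2, the lowest when a pair was left out (the highest was 3456, without pair 1), and 2229 genes when genes were counted. On array B they numbered 1790, with 986 in a fit without the intensity trend, from 628 (without pair 2) to 1968 (without pair 3) when a pair was left out, 1045 genes, 2041 with no replicate block, and 1326 to 1889 under the other alternatives. Scaling array B to a common median moved the median of all probe sets from 0.04 to -0.08 and the share of rises among changed probe sets from 47.3% to 39.5%, and the calls reported rest on the deposited scaling. Called gene lists on array A went from 11 to 0 with an estimated correlation and 3 with fry, and on array B from 4 to 0 and 2; at an unadjusted p under 0.05 the estimated correlation gave 1 list on array A, the unfolded protein response (p = 0.0292), and 0 on array B. The loss of calls with an estimated correlation cannot be laid to correlation alone, as that test has few degrees of freedom. Fry tests another hypothesis than camera, as it compares no list with other genes. Leaving out a pair gave 13 to 16 lists on array A and 3 to 5 on array B, and the other alternatives 9 to 12 and 4 to 5. At 1.5-fold in place of 2-fold in all 3 pairs, 1192 probe sets were higher and 1403 lower on array A, and 953 and 920 on array B, as a lower criterion must give; leaving out a pair, which asks less, gave 770 to 981 higher and 754 to 1034 lower on array A, and 649 to 813 and 563 to 742 on array B. These counts use no fit, so the block and the trend gave no value for them.

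Of 169 genes named on array A, 157 passed the threshold, and of 89 on array B 53 did. Without pair 1, 2 or 3, 10, 31 and 14 calls ended on array A and 6, 17 and 4 on array B, while 3, 0 and 1 were gained on array A and 2, 0 and 4 on array B. With no replicate block, 6 calls ended on array A, at adjusted p-values of 0.0515 for IFNGR1, 0.0736 for STAB1, 0.0682 for PKM, 0.0585 for SGK1, 0.0568 for SERPING1 and 0.0554 for MCM5. HLA-DQA1 (0.0459) and MCM7 (0.0284) on array A and FKBP5 (0.0425) and SRXN1 (0.0370) on array B passed with no replicate block, as each did under some of the other alternatives too. The fit with no replicate block changed no other call of a named gene or list. Without a filter 25 calls ended on array A and 8 on array B, without the trend 13 and 14, with a common median 2 and 5, and with quantile normalization 2 and 2. Leaving out a pair leaves 1 residual degree of freedom, and the total with the prior was then 11487, 74.4 and 9.59 on array A without pairs 1, 2 and 3, against 10.1 with all, and 14.4, 10.8 and 34.4 on array B, against 11.1. A gene's own spread then counts for almost nothing on array A without pair 1 and for little without pair 2. Calls of genes or lists gained there say little about stability. A call that ended there need not reflect a smaller change, as fewer arrays also raise p. Without pair 2 the log2 value of SDHC was -0.83, against -0.71 with all pairs, and that of F13A1 0.59, against 0.97. Apart from these effects of construction, the cause was not tested. No detection calls were used, so how far low signals stand above background is open, and values near the filter level of 113 on array A or 197.4 on array B are the least certain.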

Other observations

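The tests below used members of 3 lists written only after other members had been seen to fall. Those seen members were left out of the lists, so counts below are of the members left and not of whole families. The genes named here were chosen after their values were seen.

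Many ribosome assembly factors were lower with SLE serum on array A, whereas 23 of 39 cytosolic ribosomal protein genes rose there and 0 fell. Of 63 measured ribosome assembly factors on array A, 40 fell and 0 rose in the limma fit, and 58 had a negative log2 change. NOLC1, a nucleolar phosphoprotein, fell from 4172 to 1036 (log2 -1.95), NOL11 from 1642 to 435 (log2 -1.84) and the RNA helicase DDX21 from 8809 to 3598 (log2 -1.26). In the list of the TCP-1 chaperonin, which folds actin and tubulin, all 5 measured members fell. These were CCT6A (-1.73), CCT3 (-1.53), CCT5 (-1.46), CCT8 (-1.28) and CCT4 (-1.16). Of 13 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, 4 fell and 0 rose: HARS1 from 1943 to 610 (log2 -1.62), EPRS1 (-1.22), RARS1 (-1.13) and FARSA (-1.03; limma adjusted p = 0.0653 without pair 2). Without pair 3, 7 of the 13 fell. On array B, 7 of 26 ribosome assembly factors fell and 0 rose (4 fell without pair 1 and 2 without pair 2), with a median of -0.59. Of 6 synthetases there, NARS1 alone fell (log2 -0.94; adjusted p = 0.0541 without pair 1 and 0.153 without pair 2), with a median of -0.12 over the 6.

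A hypothesis is that ribosome assembly factors fell together as a group. Their median log2 change on array A was -1.07 (SD 0.62 over genes), with pair medians of -1.56, -1.14 and -0.71, which is consistent with a shared fall. The median was -1.01 or lower after quantile normalization and after scaling to a common median, which argues against the choice among these scalings as its source. All of them hold the arrays to a common level, so a shift of all transcripts could not be tested. In pair 3, where 3'/5' ratios were not higher with SLE serum, the median was -0.71. That argues against 3' bias of the RNA as the whole cause. On array A the pair medians follow the 3'/5' ratios in size, and on array B (-0.998, -0.376 and -0.409) they do not. A share of 3' bias in the fall thus stays open. The camera p was 3.5e-12 with the preset correlation and 0.175 with an estimated correlation. The latter test has few degrees of freedom, so its higher p cannot be laid to correlation alone. Whether these genes stand apart from others when their correlation is counted stays open.

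For the TCP-1 chaperonin, a shared fall is consistent with the median of -1.46, with pair medians of -1.81, -1.08 and -1.0 that also followed the 3'/5' ratios in size (camera p = 6.2e-04; p = 0.217 with an estimated correlation). For the synthetases the median of -0.51 did not decide whether the fall is shared; pair medians of -1.06, -0.42 and -0.19 followed the 3'/5' ratios of the pairs in size, and the last is that of the pair where these were not higher with SLE serum (camera p = 0.0165; p = 0.473 with an estimated correlation).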
